A study of Homo sapiens with 4 samples.

How the data were processed

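MicroRNA (miRNA) levels were measured in 4 human breast cancer cell lines, established ones by their source names, with 1 array per line. ZR-75-1 and MCF-7 formed the luminal group and MDA-MB-231 and CAL-51 the triple-negative breast cancer (TNBC) group. TNBC cells lack the oestrogen receptor, the progesterone receptor and amplified HER2. Per the labels' protocols, ZR-75-1 was grown in another medium than the other lines, RNA was extracted with TRIzol, and total RNA was dephosphorylated and ligated to a Cy3-labelled nucleotide before hybridization. The treatment notes speak of primary cultures, which conflicts with the source names, and the samples were taken as the named lines. Nothing in the labels says that the lines of one type are replicates of anything but their type, so the spread in each group is the spread between 2 different lines.

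The deposited scanner files hold spot intensity on a linear scale in 1 colour. Per the file headers, they were written by Agilent Feature Extraction version 10.7.3.1, while the submitters' processing notes give version 10.10. Per the file headers, the intensity was spatially detrended with separate background correction switched off, and the probes are placed on hg19. Each array had 56044 spots, of which 48200 were human, for 3101 probes of 1205 human miRNAs, and no spot was saturated. Probes for 142 viral miRNAs were also present. The names are those of the array design and predate the current arm-based names, with * marking the minor arm. A value table made by the authors holds log2 values. Set against the scanner files, each column equalled log2 of the software's total signal per miRNA minus 1 constant per array, with blanks where the software did not call the miRNA. The constants were 9.36 for ZR-75-1, 8.95 for MCF-7, 9.56 for MDA-MB-231 and 9.23 for CAL-51, and each lay near the 90th percentile of the detected features. The column medians were -4.95, -4.25, -4.86 and -4.46 in that order. Scale, centring and direction of that table were settled by this comparison.

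For each probe, the processed signals of the spots that were not flagged as outliers were averaged. A probe counted as detected on an array when more than 0.5 of these spots were called well above background by the scanner software, and a miRNA when any of its probes was. Signals were divided by the array's 75th percentile over the 175 probes detected on all 4 arrays. They were then raised to a floor, the median over arrays of the lowest scaled signal of a detected probe (-4.76 on the log2 scale), and log2-transformed. The level of a miRNA is that of its brightest probe by mean log2. Of 120 tested miRNAs with a second detected probe, 13 had a TNBC minus luminal difference of the other sign in that probe; miR-21, miR-19a, miR-19b and miR-301a were among them. Values at the floor have no order. Signals of different probes are not comparable as amounts, since brightness also depends on the probe.

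Human miRNAs detected on at least 2 of the 4 arrays were tested (169). TNBC and luminal lines were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The p-values are two-sided. Fixed miRNA lists with at least 3 tested members were compared with the other tested miRNAs by camera with a preset correlation of 0.01. Camera with an estimated correlation was an alternative, and fry, which tests a list against no change and not against other miRNAs, was run beside it. Where a miRNA was not well above background on any array of one group, the fold is given as a bound. This sets the mean of the brighter group against, per array of the dimmer group, the higher of the lowest detected signal and the miRNA's own signal. The lines of one type were compared by value only.

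The steps were tested on 200 simulated sets of 169 miRNAs with the real means and the fitted spread. The simulated values were not raised to the floor. The shares and sizes below therefore do not hold for miRNAs that lie at or near the floor. Of miRNAs changed 2-fold, 4-fold, 16-fold and 64-fold, 0.6%, 1.3%, 35.7% and 60.3% passed the adjusted threshold. The mean estimated sizes were 0.97, 2.09, 4.12 and 6.05 on the log2 scale for true sizes of 1, 2, 4 and 6. With no change, 11 of the 200 sets gave a call. Simulated lists of 5 members shifted by 2 on the log2 scale passed p = 0.05 in 97% of sets with the preset correlation and in 32.5% with an estimated one. Unshifted lists passed in 6% of sets, but in 25.5% when their members were correlated at 0.5.

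The miRNAs named in the text follow a rule fixed, with the lists, before the data were examined. It took 12 miRNAs in each direction with the largest TNBC minus luminal difference and both TNBC lines on the same side of both luminal lines, those past the threshold first. It further took up to 4 members of each list with the largest differences, up to 6 miRNAs in each direction between the lines of one type that differed by at least 2 on the log2 scale, and the 5 with the highest signal on each array. Other list members named to complete a list (miR-22, miR-125a-5p and miR-30b) were chosen after their values were seen. The 24 lists were the miR-200 family, miR-183 cluster, other epithelial miRNAs, miRNAs of oestrogen receptor positive tumours, miRNAs targeting ESR1, mesenchymal and invasion miRNAs, metastasis suppressing miRNAs, miR-17-92 and its paralogous clusters, the let-7 and miR-30 families, the miR-99/100 and miR-125 clusters, p53 responsive miRNAs, miRNAs of the HOX clusters, the 9p21 locus, the 17q23 amplicon of MCF-7, the pluripotency clusters led by miR-302, the chromosome 19 cluster (C19MC), the 14q32 and Xq27 clusters, the hypoxia miRNA miR-210, and markers of fibroblast and smooth muscle cells, blood cells, endothelial cells, and liver, muscle and neurons. They hold 189 different miRNAs, of which 2 (miR-106a and miR-519a) had no probe of that name.

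Alternatives tried were other scalings (all probes, quantile normalization, none), normexp background correction with an offset of 50, the sum of the probes, the software's total signal, the authors' value table (miRNAs with values on at least 3 arrays and in both groups, lists over miRNAs with values on all 4), other detection filters, a floor raised 2-fold, an intensity trend in eBayes, no test, and leaving out each array. Scaling on the median log2 signal of 4 spike-in controls was added after the data were seen. These are the controls named dmr that were detected on all 4 arrays, taken as spike-ins by their name. Positions are those the array design gives for the brightest probe and are printed only where it gives a single place. Names of genes around the miRNAs come from RefSeq's table for GRCh38 by the miRNA's name, with no coordinate carried over; 129 of the 218 miRNAs detected on at least 1 array matched 1 hairpin gene on the same chromosome. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.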

Results

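The series profiled miRNAs in 2 TNBC lines, described by the submitters as aggressive, and in 2 luminal lines described as not aggressive. It asks which miRNAs set these types apart. Luminal tumours express the oestrogen receptor and keep epithelial features, and ZR-75-1 and MCF-7 are their widely used models. MDA-MB-231 is an invasive line with mesenchymal features and CAL-51 is a TNBC line. The arrays detected 147 human miRNAs in ZR-75-1, 170 in MCF-7, 147 in MDA-MB-231 and 172 in CAL-51, or between 12.2% and 14.3% of those on the array. In all, 218 miRNAs were detected on at least 1 array and 106 on all 4. Spots of one detected probe varied by a median of 9.72% to 11.7% per array. With 1 array per line, the number of arrays limits the precision. The luminal arrays shared 1 slide and 1 scan and the TNBC arrays another, so that slide and type cannot be told apart.

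The probes for miR-720 and miR-1274b, both now regarded as fragments of tRNAs, were among the 5 brightest on all 4 arrays, and the rest of the 5 differed between arrays. miR-720 lay at 6.96 on the log2 scale in ZR-75-1, 6.93 in MCF-7, 6.75 in MDA-MB-231 and 6.28 in CAL-51. miR-21, which is raised in many tumours, was among the brightest in MCF-7 (5.62), MDA-MB-231 (4.96) and CAL-51 (2.72), and lay at 2.86 in ZR-75-1. miR-1274a was among them in MCF-7 and MDA-MB-231, let-7a in ZR-75-1 and CAL-51, let-7f and miR-200c in ZR-75-1 alone, miR-19b in MCF-7, miR-4284 in MDA-MB-231 and miR-4286 in CAL-51. Across the 169 miRNAs detected on at least 2 arrays, which are not independent replicates, the TNBC lines correlated at a Pearson coefficient of 0.857 and the luminal lines at 0.764. Of the 4 pairs of different type, MCF-7 and CAL-51 correlated highest, at 0.778, above the luminal pair, though not by Spearman coefficient (0.692 against 0.743). MCF-7 and MDA-MB-231 correlated lowest, at 0.661. Across the miRNAs detected on all 4 arrays, the Pearson coefficient was 0.850 for ZR-75-1 and CAL-51, 0.848 for MCF-7 and CAL-51 and 0.769 for the luminal pair. There the luminal pair was also lower by Spearman coefficient, at 0.728 against 0.820 for MCF-7 and CAL-51. Spearman coefficients averaged 0.767 within a type and 0.606 between types, but 0.778 and 0.763 across the miRNAs detected on all 4 arrays.

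Between the types, the miRNAs with the largest higher values in TNBC were miR-221, miR-100, miR-146a, miR-125b and miR-30a. miR-221 and miR-222, which target the cell cycle inhibitor p27 and the oestrogen receptor transcript, lie 844 bases apart on the minus strand of chromosome X within MIR222HG. The probe for miR-221 is at 45605654 to 45605671 and that for miR-222 at 45606498 to 45606509 (hg19). The level of miR-221 was 1.27 ± 0.50 in TNBC and -3.98 ± 1.11 in luminal lines (log2, mean ± SD, n = 2 each), a difference of 5.25 with a standard error of 0.74, while its second probe gave 3.31. Without ZR-75-1 the difference was 4.47, and without MCF-7 miR-221 was at least 62.8-fold higher in TNBC. Among the luminal lines it was detected only in MCF-7. miR-222 was at least 6.51-fold higher in TNBC, and miR-221* at least 3.39-fold, as neither was well above background in a luminal line. miR-100 (chromosome 11, 122022953 to 122022970, within MIR100HG) was at least 21.8-fold higher and miR-146a (chromosome 5, 159912383 to 159912400, within MIR3142HG), which dampens NF-kB signalling, at least 16.5-fold. Both differed widely between the TNBC lines, with SDs of 2.86 and 3.08, and without MDA-MB-231 the bounds were 5.36-fold and 3.64-fold. miR-125b was at 1.05 ± 0.87 in TNBC and -3.06 ± 0.08 in luminal lines, but its second probe gave a difference of 1.27 in place of 4.11. Without MDA-MB-231 the difference was 3.49 and without CAL-51 it was 4.73. The second probe of miR-30c, likewise, gave 0.61 in place of 2.63. miR-30a was at 1.03 ± 0.53 in TNBC and -2.41 ± 0.25 in luminal lines. Its other arm, miR-30a*, was at least 6.05-fold higher in TNBC. The remaining miRNAs of this group were miR-130a, miR-30c and miR-99b, with differences from 1.25 to 2.65, and miR-30e*, which was at least 2.04-fold higher. Within it, miR-130a was near 0 in 3 lines and not well above background in MCF-7, without which its difference was 0.36. Without CAL-51, the bound of miR-30a* was 4.02-fold. Its second probe gave a difference of 2.29, and that of miR-221* gave 1.19.

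The miRNAs with the largest lower values in TNBC were led by the miR-200 family, which represses the transcription factors ZEB1 and ZEB2 and holds cells in an epithelial state. miR-200c and miR-141 lie 410 bases apart on the plus strand of chromosome 12 (probes at 7072914 to 7072927 and 7073324 to 7073339) within MIR200CHG. miR-200c was at 3.34 in ZR-75-1 and -0.63 in MCF-7, at -4.20 in CAL-51 and not well above background in MDA-MB-231. Its TNBC minus luminal difference was -5.83 with a standard error of 1.53, or -3.85 without ZR-75-1. miR-141, at 2.57 in ZR-75-1 and -0.61 in MCF-7, was at least 53.5-fold lower in TNBC, or at least 17.7-fold without ZR-75-1, and its second probe gave a difference of -3.71. The other 3 members, miR-200b, miR-200a and miR-429, lie on the plus strand of chromosome 1 between 1102546 and 1104456 within MIR200BHG. Their differences were -2.53, -2.76 and -2.03, or -1.74, -2.13 and -1.75 without MDA-MB-231, and their second probes gave -2.002, -1.23 and -1.99. Of the 5 members, MDA-MB-231 had 1 well above background (miR-200b) and CAL-51 had 4. miR-148a (chromosome 7, 25989585 to 25989603), at 1.59 in ZR-75-1 and -1.14 in MCF-7, was at least 31.8-fold lower in TNBC, or at least 12.3-fold without ZR-75-1, and its second probe gave -4.31. miR-196a, encoded in the HOX clusters, was at least 28.0-fold lower, or 17.1-fold without ZR-75-1, though its second probe gave -1.62. miR-363 was at least 4.04-fold lower, or 2.11-fold without ZR-75-1. Differences of miR-193a-3p, miR-4306, miR-425 and miR-185 ran from -2.25 to -1.83, and from -1.38 to -0.98 without ZR-75-1; the second probe of miR-185 gave -1.01.

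**Figure D1:**
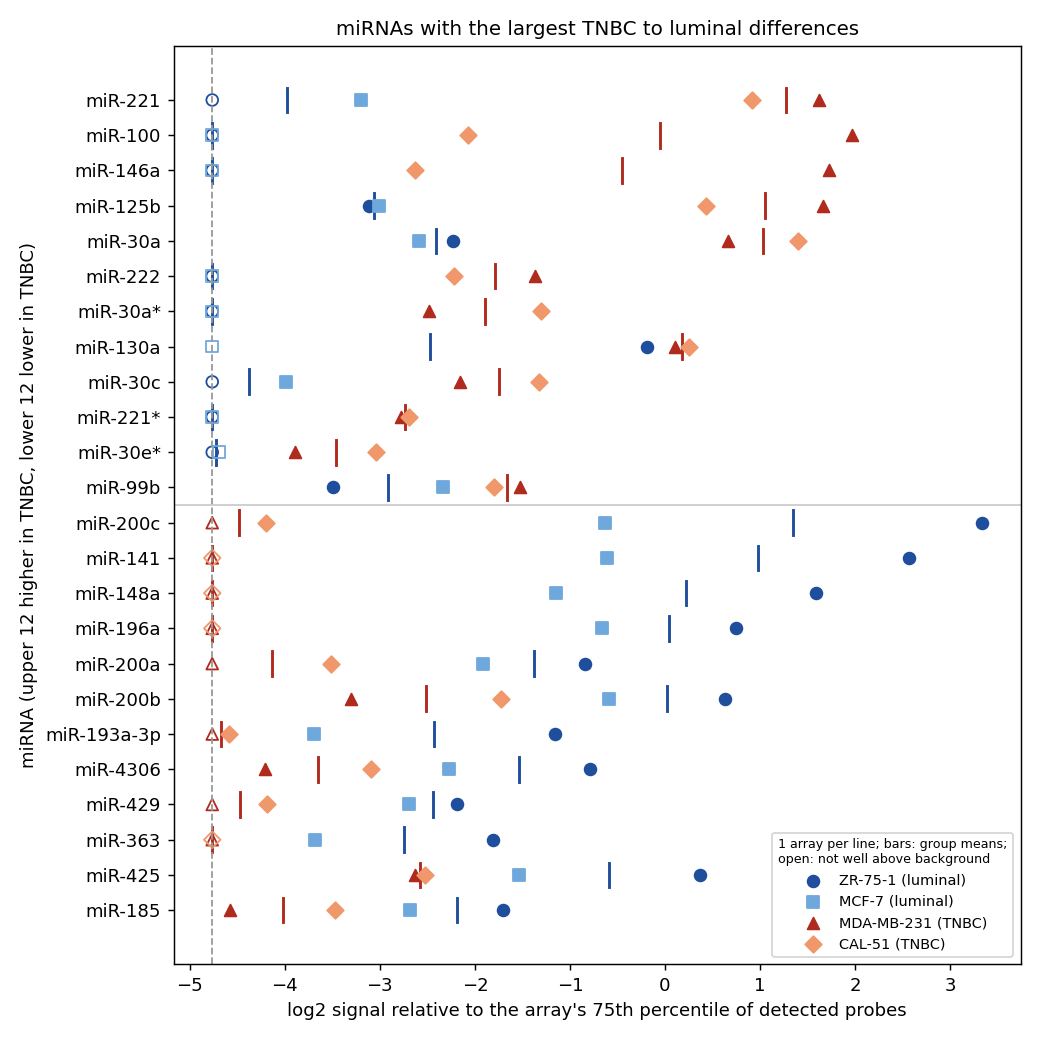
Levels of the 24 miRNAs with the largest differences between the types, as log2 signal relative to each array's 75th percentile of detected probes (horizontal axis), with 1 point per cell line. Vertical bars are group means (blue luminal, red TNBC), open symbols are not well above background, and the dashed line is the floor at -4.76. miR-141, miR-148a, miR-196a and miR-363 are open in both TNBC lines, while miR-100, miR-146a, miR-222, miR-30a*, miR-221* and miR-30e* are open in both luminal lines.

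None of these differences passed the test. Of 169 miRNAs, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.135 (miR-196a, miR-221, miR-30a and miR-125b). At an unadjusted p under 0.05 there were 17 miRNAs, 8 higher and 9 lower in TNBC, where 8.45 are expected with no difference. Besides 15 of the 24 miRNAs above, these were miR-497 and miR-1275, named here after their values were seen. The split was 12 higher and 4 lower with scaling over all probes, and the count was 10 without MDA-MB-231 and 4 over miRNAs detected on all 4 arrays. In 22 miRNAs both TNBC lines lay above both luminal lines and in 51 both lay below, together 43.2% against 33.3% by chance. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333. The median difference over all tested miRNAs was -0.42 and moved between -0.61 and 0.11 with the scaling and probe summary. A difference near that size therefore carries no direction. Each of the 24 miRNAs kept its sign in all settings in which it was measured. Leaving out 1 array could not change it, as they were chosen with both TNBC lines on one side of both luminal lines. The other settings process the same 4 arrays again.

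P-values here measure the spread between lines, since nothing in the labels names separate cultures of one line. Where both arrays of a group lay at the floor, that group's SD was 0 because of the floor. Among others, this holds for miR-196a, miR-141 and miR-148a in TNBC and for miR-100, miR-222, miR-221* and miR-30a* in luminal lines. Their p-values do not hold the full spread between lines and may be too small. Among the lists fixed beforehand, the miR-200 family fell against the other miRNAs in TNBC (camera, adjusted p = 0.000986). The call was lost with the correlation estimated, at 0.81 (adjusted p = 0.485). Fry, which asks whether a list moves at all and not against other miRNAs, did not call it (adjusted p = 0.257). All 5 members were lower in both TNBC lines, by a median of -2.76 against -0.42 for all tested miRNAs. All 5 passed when adjusted over the list alone, and 0 over all miRNAs tested. The mesenchymal and invasion list rose (adjusted p = 2.89e-06). This call too was lost with the correlation estimated, at 0.45 (adjusted p = 0.428), and fry made none (adjusted p = 0.291). Of its 10 tested members, both TNBC lines were above both luminal lines in 6 and below in 0, with a median of 2.38, or 2.25 with bounds. Besides miR-221, miR-222, miR-100, miR-125b and miR-146a, the sixth was miR-22, at 0.76. Against the list's name, miR-10b and miR-21 were at -1.12 and -0.40 and had no common side, and miR-21 was at 0.19 with scaling over all probes and at 1.22 in its second probe. Adjusted over the list alone, 3 members passed. The miR-99/100 and miR-125 clusters rose as well (adjusted p = 0.000263, median 1.25). Their call was lost with the correlation estimated (adjusted p = 0.428). The estimate was only 0.06, so this loss does not show correlated members. Fry made no call (adjusted p = 0.151). Both TNBC lines were above both luminal lines for 4 of 5 members, namely miR-100, miR-125b, miR-99b (1.25) and miR-125a-5p (0.82). The fifth, miR-99a, was at 1.23 with MDA-MB-231 between the luminal lines, and 1 member passed when adjusted over the list alone. The last 2 lists share miR-100 and miR-125b.

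The miR-30 family rose (adjusted p = 0.0385, median 0.49), but not with the correlation estimated, at -0.17 (adjusted p = 0.428). Fry made no call (adjusted p = 0.151). The rise was carried by miR-30a and miR-30c, while miR-30e (-0.16 without ZR-75-1), miR-30b and miR-30d were at 0.49, -0.11 and -0.73. Adjusted over the list alone, 2 members passed. The list of miRNAs targeting ESR1, the gene of oestrogen receptor alpha, also rose (adjusted p = 0.0385), with a mean of 1.11 but a median of only 0.14. It did not with the correlation estimated, at 0.02 (adjusted p = 0.428), and fry made no call (adjusted p = 0.299). For these lists too, estimates this low do not show correlated members. Its mean was 0.38 without ZR-75-1 and 1.85 without MCF-7. In the value table of the authors it was -0.29 and over miRNAs detected on all 4 arrays -0.38. These last 2 settings keep only members measured on all 4 arrays and so leave out miR-221 and miR-222, which carry the rise. Of its 6 tested members, miR-221 and miR-222 passed when adjusted over the list alone. miR-22 was above both luminal lines too. Like miR-221 and miR-222, it is also in the mesenchymal and invasion list, so the rises of these lists are not independent. The remaining ESR1 list members had lower means in TNBC. They were miR-18b (-0.99, but 0.63 without MCF-7), miR-18a (-0.48, but 1.59 without MCF-7) and miR-193b (-0.84, or -0.31 without MDA-MB-231). This list lost its call in 12 of 16 alternative settings and the miR-30 family in 9 of 16. Both lost it without any 1 array, with adjusted p from 0.0502 to 0.173 and from 0.0625 to 0.164. Of the 12 lists, 0 passed with an estimated correlation and 0 by fry. Over the 64 tested members of all lists, 0 passed and the smallest adjusted p was 0.0510.

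**Figure D2:**
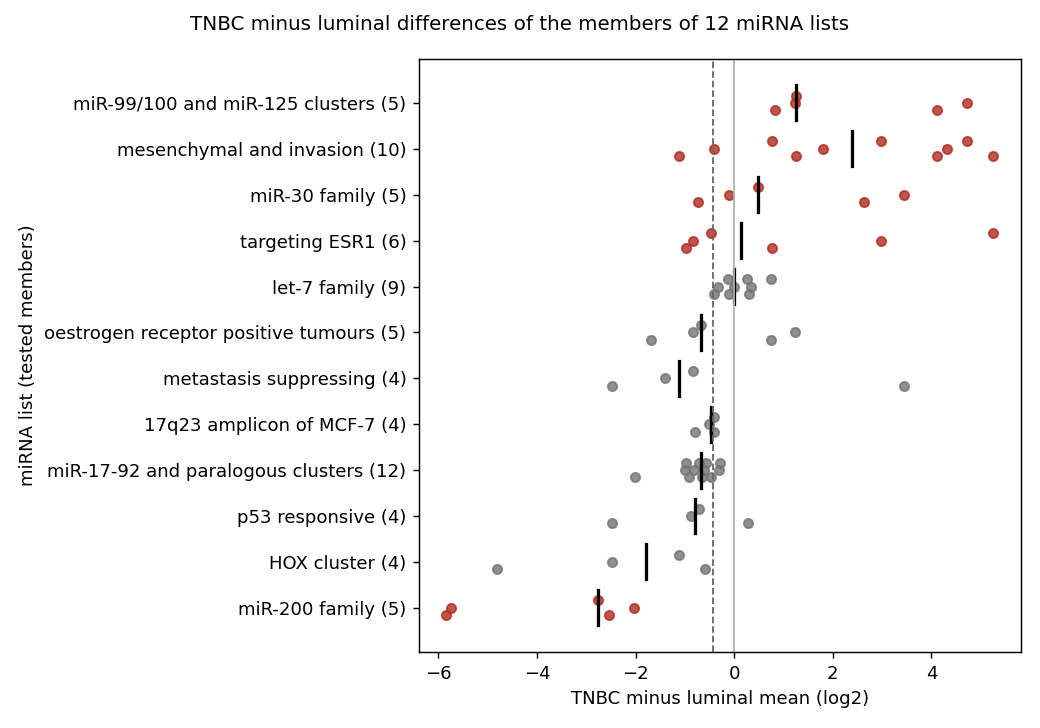
TNBC minus luminal difference (log2, horizontal axis) of every tested member of the 12 lists with at least 3 tested members (number in parentheses), 1 point per miRNA. Red lists passed camera with its preset correlation, grey lists did not, black bars are medians and the dashed line is the median of all tested miRNAs at -0.42. The 5 members of the miR-200 family lie between -5.83 and -2.03.

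The other 7 lists tested did not pass. Without ZR-75-1, the let-7 family and the miR-17-92 clusters did (adjusted p = 0.000426 and 0.0108), with means of 0.97 and -1.78. The HOX list passed with scaling over all probes (adjusted p = 0.0407). With no filter on detection 6 of the 7 passed, all but the metastasis suppressing list. That setting compares the lists with all 1205 human miRNAs, of which only 218 were detected on any array. Its calls therefore do not show a shift against other measured miRNAs. The 9 members of the let-7 family, which act against growth, had no common side in any member, a median of -0.0022 and a mean of 0.08, which was -0.03 with the sum of the probes and was -0.81 without MCF-7. The miR-17-92 clusters, which promote proliferation, had a median of -0.68 over 12 members, 2 of them below both luminal lines (miR-363 and miR-106b at -0.99), and a mean that was 0.22 without MCF-7. The oestrogen receptor positive list had a median of -0.67, with miR-342-3p at -1.69, or -0.56 without MDA-MB-231, where it was not well above background. miR-99a and let-7c were at 1.23 and 0.75, but at -0.17 and -0.45 without CAL-51, and let-7c was at -0.56 without MCF-7. Its mean was -0.25, but 0.34 with scaling over all probes, 0.15 with quantile normalization and 0.05 with no scaling. For p53 responsive miRNAs the median was -0.79, for the HOX clusters -1.79 and for the 17q23 amplicon -0.47, with miR-454 at -0.79; the mean of the last list was 0.03 with scaling over all probes. Of the HOX miRNAs, miR-196a passed when adjusted over the list alone, and miR-10a, miR-10b and miR-196b were at -2.47, -1.12 and -0.58. Without MCF-7, miR-10a was at -0.12. The other 2 were then higher in TNBC, with fold bounds of 3.70 for miR-10b and 2.98 for miR-196b and MDA-MB-231 at the floor. Without MDA-MB-231, miR-10b and miR-196b were at 0.83 and 1.06. The metastasis suppressing list had a median of -1.12 and a mean of -0.32, while camera placed it upward (adjusted p = 0.844), and the mean was 0.23 with scaling over all probes. Its members miR-34a (-2.47, or -0.17 without MDA-MB-231), miR-126 (-1.40, or -0.55 without MCF-7) and miR-193b had lower means in TNBC and miR-30a a higher one, which passed when adjusted over the list alone. Of the miR-183 cluster, miR-183 and miR-96 were at -1.41 and -1.32, with both TNBC lines below both luminal lines. For miR-183, CAL-51 at -2.60 and MCF-7 at -2.58 were near equal, and the difference was -0.48 without MDA-MB-231. For miR-96 it was -0.81 without ZR-75-1.

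Several loci were not detectable at this signal level. miR-31 and miR-31* of the 9p21 locus, the pluripotency clusters, C19MC, the Xq27 cluster and the liver, muscle and neuron markers were not well above background in any line. Of 35 miRNAs of the 14q32 cluster, only miR-494 was detected, at a difference of 0.01. The hypoxia miRNA miR-210 was detected in all 4 lines, at a difference of -0.38 that was 0.21 with scaling over all probes. Of 7 fibroblast and smooth muscle markers, 3 were detected (miR-143, miR-145 and miR-199a-3p, named after their values were seen), all in CAL-51 alone and near the floor. Of 8 blood cell markers, only miR-486-5p was detected, in MCF-7 and CAL-51. The endothelial marker miR-126 was detected in every line but CAL-51. Of the other epithelial list, miR-192 was tested (-0.87, but at least 1.30-fold higher in TNBC without MCF-7), and miR-375 was detected only in ZR-75-1.

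Differences between lines of one type come from 1 array per line and have no test. Between ZR-75-1 and MCF-7, 34 of 218 miRNAs differed at least 4-fold, and 72 did with the total gene signal of the scanner software. The scaled spike-in controls lay 0.42 to 1.16 apart between these arrays (log2), against 0.04 to 0.28 between the TNBC arrays. How far this adds to the differences between the luminal lines was not tested. Of the 5 HOX cluster miRNAs, 3 were higher in MCF-7, with miR-10b at least 67.2-fold, miR-10a (chromosome 17, 46657224 to 46657243, within HOXB3) 25.9-fold and miR-196b at least 20.8-fold higher. The others were higher in ZR-75-1, miR-196a by 2.67-fold and miR-615-3p, named after its values were seen, by at least 2.22-fold. miR-18a and miR-19a of the miR-17-92 cluster in MIR17HG on chromosome 13 were 17.7-fold and 15.0-fold higher in MCF-7, and miR-218 at least 14.4-fold. The median of the 12 miR-17-92 members was -2.27 for ZR-75-1 minus MCF-7. miR-21, in the gene VMP1 in the 17q23 region amplified in MCF-7, was at 5.62 in MCF-7 and 2.86 in ZR-75-1. Of the other 17q23 list members, miR-21* and miR-301a were 5.83-fold and 2.02-fold higher in MCF-7. miR-454 was 1.16-fold higher in ZR-75-1. Copy number was not measured. ZR-75-1 was higher in miR-130a (at least 17.2-fold), miR-200c (15.6-fold), let-7b (11.4-fold), miR-375 (at least 6.61-fold), miR-141 (9.10-fold) and miR-181a (6.91-fold). The let-7 family had a median of 1.49 for this pair.

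MDA-MB-231 and CAL-51 differed at least 4-fold in 18 of 218 miRNAs, 9 in each direction, and in 36 with the total gene signal. MDA-MB-231 was higher in miR-146a (20.5-fold), miR-100 (16.5-fold), miR-29a (8.45-fold), miR-224 (at least 7.65-fold), let-7i (6.78-fold) and miR-29b (6.49-fold). CAL-51 was higher in miR-34a, a direct target of p53 (chromosome 1, 9211751 to 9211769, within MIR34AHG), by 24.3-fold, and in miR-10b by at least 14.9-fold. It was also higher in miR-196b (at least 9.69-fold), miR-1260b (7.91-fold), miR-99a (6.90-fold) and miR-301b (at least 5.28-fold). The mesenchymal and invasion list had a median of 1.74 for MDA-MB-231 minus CAL-51 and the oestrogen receptor positive list one of -2.25. miR-10b and miR-196b were thus detected in MCF-7 and CAL-51 and in neither ZR-75-1 nor MDA-MB-231.

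**Figure D3:**
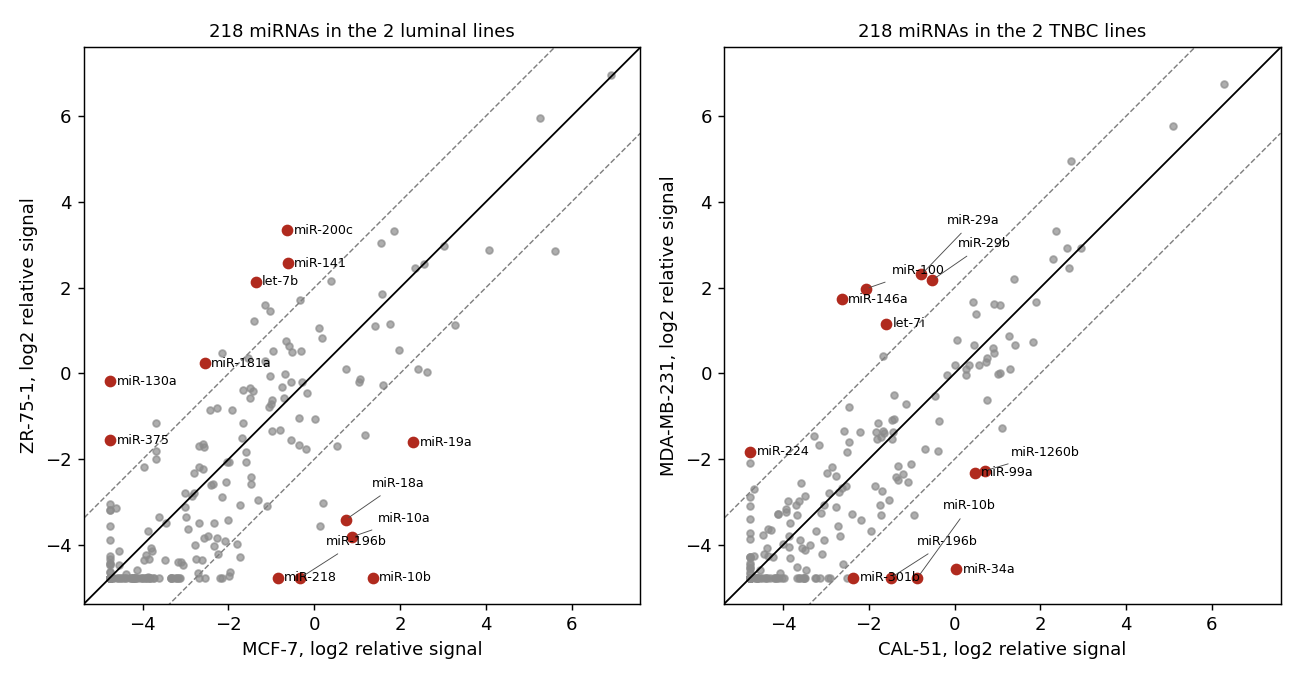
Levels of the 218 miRNAs detected on at least 1 array (log2 signal relative to each array's 75th percentile of detected probes) in one line of a type against the other. The left panel shows ZR-75-1 against MCF-7 and the right panel MDA-MB-231 against CAL-51. Each point is 1 miRNA, dashed lines mark 4-fold differences and the red points are the 6 largest in each direction. More miRNAs lie outside the dashed lines for the luminal pair (34) than for the TNBC pair (18). Spike-in controls also lay further apart between the luminal arrays.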

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

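The tests in this part were fixed before their values were seen. Probes for viral miRNAs were set aside as a background set, and 6 of 142 viral miRNAs (4.23%) were above background on at least 1 array, against 18.1% of human ones. Per array there were 2 in ZR-75-1, 5 in MCF-7, 5 in MDA-MB-231 and 1 in CAL-51. The scanner software's own calls gave 8, 9, 7 and 5 viral miRNAs in that order. The highest signal was that of ebv-miR-BART13 in MCF-7, at 150.1 against 10.3 to 12.9 in the other lines. The groups give no biological explanation for it. A viral genome in the cells, which the groups do not name, would bring many miRNAs of one virus. At most 4.55% of the 44 EBV miRNAs were above background on an array, which argues against an EBV genome. Of the 6 viral miRNAs, 3 were of HSV and 1 of KSHV. No such share was computed for these viruses, so they were not tested. Viral probes above background had a median GC content 17.9 percentage points above that of the other viral probes (75% against 57.1%). This is consistent with cross-hybridization of GC-rich probes to other RNA.

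The count of 17 miRNAs at an unadjusted p under 0.05 was weighed next. The 3 ways to split the 4 arrays into 2 and 2 are too few to give a share under 0.05. The real split gave 17 and the highest of the others 11 (as large a count in 1 of 3 splits). Simulated sets with no change averaged 9.05 such miRNAs and reached 17 in 0.5% of sets. Their miRNAs vary independently and were not raised to the floor, unlike those of the arrays, so this share excludes nothing. The spike-in control probes were used to weigh a slide difference in labelling or hybridization yield. They were scaled like the miRNAs, so a yield difference shared by all probes cancels from both. Over the 4 controls, the median size of difference between the group means was 0.26 on the log2 scale and the largest 0.49. Between the luminal arrays of the same slide they lay up to 1.16 apart, and between the TNBC arrays up to 0.28. The median over the 17 miRNAs was 2.97. The spike-in values all lie below it. Because a shared yield difference cancels in the scaling, they cannot decide whether yield plays a part. Any slide effect, in yield or otherwise, the growth medium of ZR-75-1 and differences between single lines stay open. So does the type itself, which cannot be told apart from the slide.

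Several miRNAs with GC-rich probes, such as miR-1275 (probe GC 71.4%), had looked low on both TNBC arrays. Over the 34 tested miRNAs with a probe GC above 60% the median difference was -0.42, the same as over the other 135. Both TNBC lines were below both luminal lines in 13 of the 34 and above in 3, against 38 and 19 of the others. The medians show no trend with GC, while these counts lean further downward for GC-rich probes, a difference that was not tested. Viral probes detected on at least 2 arrays gave a median of -0.33 but lie within 0.34 of the floor in the median. With scaling on the spike-in probes, the GC-rich miRNAs were at -0.26 and the others at -0.27. Scaling applies the same factor to every probe of an array and moved both sets alike, so it cannot bear on a difference linked to GC. The viral probes lie too near the floor to decide whether the background differs between slides.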

How the results depend on the processing

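No paired analysis was possible because the replicate numbers only name different cell lines. A fit with the slide as a term could not be made, as each slide holds 1 type. Scaling on the spike-in probes was chosen after seeing the data and the other settings before. All 16 refits (scaling, background, summary, filters, floor, each array left out) and the intensity trend gave 0 miRNAs past the threshold. A 2-fold minimum on top cannot change a count of 0. Without a test, 20 miRNAs differed at least 2-fold between every TNBC and every luminal line. The count of 17 at an unadjusted p under 0.05 became 26 with the floor raised 2-fold, 10 in the value table of the authors, 4 among miRNAs detected on all 4 arrays, and 10 to 22 with 1 array left out, the lone array being assumed to vary like the others. The 5 list calls became 0 with an estimated correlation and 2 over miRNAs detected on all 4 arrays. They became 3 with the total gene signal, the value table and the floor raised 2-fold. With no filter there were 11. These were 9 of the 12 lists tested, without the ESR1 and miR-30 lists, and 2 that had too few members before. Most miRNAs in that setting were detected on no array, so its calls do not show a shift against other measured miRNAs. With 1 array left out, the lists called were not all the same. Without ZR-75-1, the ESR1 and miR-30 lists dropped out. The let-7 and miR-17-92 lists came in, with means of 0.97 and -1.78. Fry, which tests a list against no change, called 0. The mesenchymal list and the miR-99/100 and miR-125 clusters passed camera with its preset correlation in all 16 settings and the miR-200 family in all 14 in which 3 members were measured. At least 4-fold differences between lines became 36 for TNBC and 72 for luminal lines with the total gene signal, and the mean Spearman correlation between types 0.76 over miRNAs detected on all 4 arrays. The causes were not tested, except that stricter filters leave fewer miRNAs.

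Of 829 values of 54 named miRNAs under alternatives, 784 kept their sign and 45 (18 miRNAs) changed sign, and none passed the adjusted threshold. Whether the TNBC lines stayed on one side of the luminal lines was not checked here. Scaling over all probes gave let-7d 0.19, miR-98 0.27, miR-301a 0.0727, miR-21* 0.11, miR-21 0.19, miR-210 0.21, and list means of 0.34 (oestrogen receptor positive), 0.23 (metastasis suppressing) and 0.0337 (17q23). Quantile normalization gave miR-98 0.19, miR-21 0.0032, miR-210 0.0032, and lists 0.15 (oestrogen receptor positive) and 0.0356 (metastasis suppressing). The oestrogen receptor positive list was at 0.0485 with no scaling. Normexp gave miR-34b* -0.00793, miR-494 -0.0352 and miR-486-5p -0.0529. The sum of the probes gave miR-494 -0.18, miR-486-5p -0.0526 and the let-7 list -0.0332. The total gene signal gave miR-494 -0.0669 and miR-486-5p -0.86. The value table gave miR-34b* -0.10, the ESR1 list -0.29 and the metastasis list 0.10. Over miRNAs detected on all 4 arrays, the oestrogen receptor positive list was at 0.12, the ESR1 list at -0.38 and the metastasis list at 0.0455. The ESR1 list turned in these 2 settings because they leave out miR-221 and miR-222.

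With 1 array left out, let-7d ran from -1.45 to 0.64, miR-98 from -1.12 to 0.47, miR-30e from -0.16 to 1.14, miR-494 from -0.77 to 0.79, miR-192 from -2.17 to 0.44, let-7c from -0.56 to 2.06, miR-18b from -2.60 to 0.63, miR-19b from -1.999 to 0.16, let-7i from -1.04 to 1.72, miR-34b* from -0.71 to 1.28, miR-10b from -4.18 to 1.95, miR-196b from -2.80 to 1.64, miR-21* from -1.76 to 0.92, miR-21 from -1.79 to 0.98, miR-301a from -1.07 to 0.0342, miR-99a from -0.17 to 2.62, miR-210 from -1.13 to 0.36 and miR-486-5p from -0.32 to 1.18. The upper ends of miR-192, miR-10b and miR-196b and the lower ends of miR-486-5p and miR-21* have 1 group at the floor and are not exact. The fold bounds of miR-192, miR-10b, miR-196b and miR-486-5p were 1.30, 3.70, 2.98 and 1.25 in that order. None was set for miR-21*, which counted as detected in CAL-51 although its value there lay at the floor. List means ran from -1.08 to 0.59 (oestrogen receptor positive), -1.78 to 0.22 (miR-17-92), -0.81 to 0.97 (let-7), -1.30 to 0.23 (17q23) and -1.07 to 0.44 (metastasis suppressing). Signal over background limits detection: 12.2% to 14.3% of human miRNAs were detected per array. The software's own calls gave 194, 207, 179 and 203 and stayed within 1.5 times the counts reported, as did requiring every spot or any spot above background.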

Other observations

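miRNAs that lie together in the genome had like profiles over the 4 lines. Shared transcription was the hypothesis, and its test was fixed before its values were seen. Of 125 tested miRNAs with a single position, 35 pairs lay within 10 kb on one strand. The median correlation of their centred profiles was 0.93, against 0.15 for randomly placed pairs (95% range -0.17 to 0.47; permutation p = 0.0001, the smallest that 10000 permutations can give). It was also 0.93 over the 27 pairs more than 150 bases apart, which leaves out the arms of one hairpin. miR-200c and miR-141 correlated at 0.995, miR-18a and miR-19a at 0.998, and miR-221 and miR-222 at 0.973. Not every pair followed: let-7e correlated at -0.51 with miR-99b and at -0.24 with miR-125a-5p, its neighbours on chromosome 19, while these correlated at 0.93 with each other. miR-363 correlated at -0.16 with miR-18b and -0.18 with miR-20b on chromosome X, although miR-18b and miR-20b correlated at 0.998. The values may reflect shared transcription, but some pairs belong to one sequence family and pairs of one cluster are not independent. For let-7e and miR-18b, cross-hybridization with family members was not tested.

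Of the 5 HOX cluster miRNAs, miR-10b and miR-196b ran across the types. miR-10b lay at 1.37 in MCF-7 and -0.86 in CAL-51, and miR-196b at -0.32 and -1.49, with neither well above background in ZR-75-1 or MDA-MB-231. The other 3 did not share this split: miR-196a was detected in the luminal lines alone, miR-10a in every line but CAL-51 and miR-615-3p in ZR-75-1 alone. The split of the arrays that sets MCF-7 and CAL-51 against ZR-75-1 and MDA-MB-231 gave 11 miRNAs at an unadjusted p under 0.05.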
